A study of Homo sapiens with 2 samples.

How the data were processed

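Total RNA expression was measured in HCT116 cells, an established human colon carcinoma line, on 2 Agilent whole-genome arrays of 1 colour (Cy3). 1 array held the parental line and 1 array held a derivative that the labels call resistant to 5-FU (5-fluorouracil), grown in rising concentrations of the drug over months. The labels describe the comparison as one of basal expression. Groups came from the labels alone, with 1 array in each. Both arrays lay on 1 slide and came from 1 scan, so slide and scan could not differ between the groups.

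The deposited scanner files give 1 row per spot. Their intensities are on a linear scale and were produced with Agilent Feature Extraction 10.7.3.1 per the file headers, after background subtraction by that software. The software's processed intensity, its error per spot and its flags for outliers, saturation and signal well above background were used as the authors deposited them. The deposited series matrix also holds linear intensities, and its median was 12.51 on both arrays. How the authors made it is not given in the sources used here. Its sorted columns differed by at most 1.78 percent, as they would after a quantile normalization. Over probes well above background, its log2 difference between the arrays correlated with that of the scanner values at r = 0.996 across probes, which bore out its direction. It was kept as an alternative.

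Control spots were left out, which kept 58717 spots of 42405 probes. Of these probes, 34085 were spotted once, 7321 were spotted 2 times and 999 were spotted 10 times. Spots that the software marked as outliers were left out, 414 on the parental and 362 on the resistant array. No spot was saturated. Each log2 intensity had the 75th percentile of its array subtracted, and the spots of a probe were averaged. A probe counted as well above background where over 50 percent of its unflagged spots did. The arrays' own annotation uses the build hg19. Gene symbols came from the RefSeq accession of each probe, without version, through a table of the assembly GRCh38.p14, which served only for names and for the order of neighbouring genes. Accessions of 25715 probes matched 19720 symbols, and 16690 probes stayed unnamed. A gene was represented by its brightest probe among those well above background on both arrays, and the report gives the other probes of a named gene where any differed from it by over 2 spot errors.

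Differences are resistant minus parental on the log2 scale. With 1 array per group no test could be made, so no p-value is given and no difference has a replicate check. The error given is the software's spot error carried to the difference, with a median of 0.21. The SD of probes with at least 8 usable spots on an array had a median of 0.09 on each, which corresponds to 0.12 on the difference. Both errors leave out the spread between cultures, and the number of arrays limits the precision. Genes were counted at a difference of 1 or more in size, which is 2-fold. A gene well above background on 1 array only was given a bound: its bright level over the higher of its own dim level and the lowest level well above background on the dim array. Medians over lists of genes, and over windows of 25 neighbouring genes, were compared with 10000 random lists matched on mean level in 20 bins and with 1000 shuffles of gene order. These percentiles describe the 2 arrays and do not test the conditions. A list stood apart outside the central 95 percent of its random lists. Of 31 lists fixed in advance, 29 had the 5 measured genes needed for a percentile. About 1 or 2 of them would stand apart by chance if genes varied independently. The random lists draw genes singly, so this figure does not hold for lists whose genes vary together.

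Named genes were chosen by a rule written in advance. It took the 12 largest differences per direction among genes over 3 spot errors, at or above the 25th percentile of level, with a plain symbol and not Y-linked. It also took the 4 largest bounds per direction, up to 4 genes per list, up to 3 genes in each of the 3 most extreme windows, and a fixed set around 5-FU chosen whatever its value. Some genes that the rule takes are not reported here. On simulated arrays with the real levels and spot errors, run over 11484 genes, the size rule recovered 2 percent of 50 genes changed 1.5-fold, 46 percent of 50 changed 2-fold, and 100 percent of 50 changed 3-fold and of 50 changed 4-fold. It called 4 of 11214 unchanged genes. In the same simulation 5 of 100 unchanged lists stood apart. The simulated noise was the spot error alone, drawn for each spot independently. It left out the spread between cultures, errors of single probes and genes that vary together. These numbers are therefore not rates of false calls on the real arrays. Alternatives fixed before the data were examined were normexp background correction with an offset of 50, median, quantile, cyclic loess and spike-in scaling, no filter and a stricter filter on dim probes, the mean of a gene's probes, the series matrix, a limit of 3 spot errors, windows of 15 and 51 genes, and unmatched random lists. The mean spot signal was not among the columns used here, so normexp ran on the median signal. Leaving out saturated spots moves nothing, since there were none. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp, quantile and loess.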

Results

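Basal gene expression was compared between parental HCT116 colon carcinoma cells and cells of the same line selected for resistance to 5-FU, a fluorinated pyrimidine that inhibits thymidylate synthase and is built into RNA and DNA. The comparison asks which transcripts differ in the resistant cells without acute treatment. There was 1 array per group, so every value below describes a pair of arrays, with the spot error as its only error. The 75th percentile of the processed signal was 125.0 on the parental and 127 on the resistant array, and 52.4 and 51.7 percent of spots were well above background. The lowest probe signals called well above background were 9.59 and 11.3.

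Of 11484 named genes measured on both arrays, 360 were at least 2-fold lower and 296 at least 2-fold higher in the resistant cells, and 94.3 percent lay within 2-fold. The lowest was ACSL5, an enzyme that activates long-chain fatty acids, at -4.83 ± 0.23 on the log2 scale (28.5-fold lower). S100A14, a calcium-binding protein of epithelia, was at -3.54 ± 0.21, and FXYD3, a regulator of the sodium pump, at -2.93 ± 0.23. DDIT3 and TRIB3, which are induced under amino acid and endoplasmic reticulum stress, were 6.00-fold and 5.31-fold lower. ABCC3, an exporter of organic anions, was 5.29-fold lower, and its other probe gave -1.44. The remaining genes of the 12 lowest were RINL at -2.65, LEMD1 at -2.45, VGF, a neuropeptide precursor, at -2.44, the adhesion receptor ADGRF1 at -2.22, the Golgi calcium pump ATP2C2 at -2.17 and the ileal bile acid-binding protein FABP6 at -2.15.

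**Figure D1:**
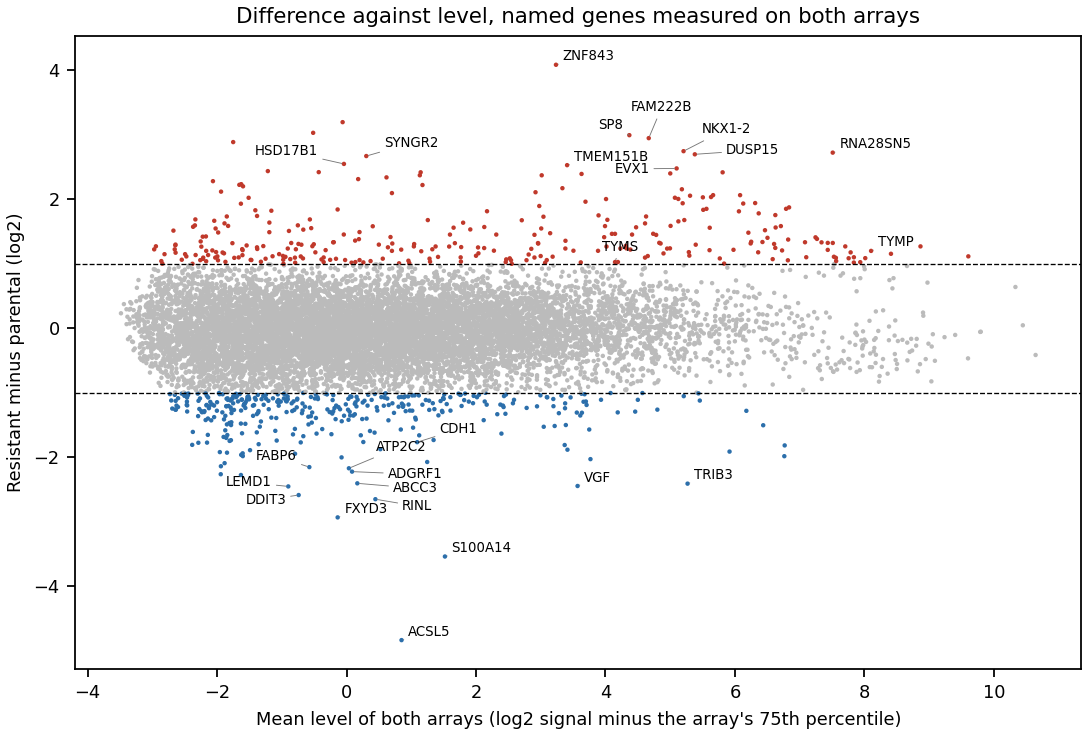
Each point is a named gene measured on both arrays. The x axis is the mean log2 signal of both arrays relative to each array's 75th percentile, and the y axis is resistant minus parental on the log2 scale, with dashed lines at 1 and -1. Red points are the 296 genes at least 2-fold higher and blue points the 360 at least 2-fold lower, and ACSL5 lies lowest at -4.83.

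The highest gene, the zinc finger gene ZNF843, was at 4.09 ± 0.20 (17.0-fold higher), and the 12 highest also held the homeobox genes NKX1-2 at 2.75 and EVX1 at 2.48, the zinc finger factor SP8 at 3.00, and FAM222B at 2.95. DUSP15 was at 2.70, SYNGR2 at 2.67, the oestradiol-producing enzyme HSD17B1 at 2.55 and TMEM151B at 2.53. Of the 42 genes at least 4-fold higher 32 rested on a single probe, as did 18 of the 19 at least 4-fold lower. Probe sequences were not used here, so cross-hybridization of these probes was not tested. RNA28SN5, a 28S ribosomal RNA gene, was at 2.72, and its other 3 probes lay between 1.52 and 2.33. The single probes of 18S and 5.8S ribosomal RNA gave -0.18 and 0.28. FAM222B had a 2nd probe at -0.01. Among genes at least 2-fold higher with several measured probes, the other probes had a median of 0.5 or more in 24 of 79 genes. In 25 of these 79 genes the other probes had a median of 0 or below. Among genes at least 2-fold lower, the other probes were lower by a median of 0.5 or more in 27 of 51 genes. In 11 of these 51 their median was 0 or above.

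Higher genes made up 45.1 percent of the genes past 2-fold in the main setting. The share was 41.1 percent with median scaling, 42.4 percent with quantile normalization, 44.7 percent with cyclic loess, 44.2 percent with the percentile taken over detected spots, 41.9 percent with the mean of a gene's probes and 39.3 percent in the series matrix. It passed 50 percent with scaling on the 10 spike-in probes, which moved all genes up by 0.15 (66.4 percent), with normexp background correction (64.0 percent), with the stricter filter on dim probes (57.4 percent) and with no such filter (50.7 percent). All values here are relative to the 75th percentile.

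A further 869 genes were well above background on 1 array only. The bound reached 2-fold for 98 genes in the direction of the resistant cells and for 115 in the direction of the parental cells. C1QTNF1 was at least 20.9-fold, AKNA at least 13.0-fold, TSHZ2 at least 7.92-fold and KCNG3 at least 7.81-fold higher in the resistant cells. KNDC1 was at least 17.98-fold, the receptor subunit IL20RB at least 9.65-fold, the protease inhibitor CSTA at least 8.002-fold and ZBED2 at least 6.39-fold lower.

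Among the genes that handle 5-FU, several were higher. TYMS, thymidylate synthase, was at 1.03 ± 0.20 (2.04-fold higher), though it lay just under 2-fold after median scaling (0.997), quantile normalization (0.97) and normexp (0.97) and in the series matrix (0.87). DUT, which removes dUTP, was at 0.89. In the thymidylate and folate list, 2 of 19 measured genes were at least 2-fold higher and none lower, SLC46A1, a folate transporter, was at -0.67, and the median was 0.02 (percentile 62.9). In the list of 5-FU activation and catabolism, TYMP, thymidine phosphorylase, was at 1.20 ± 0.20 and TK1, thymidine kinase, at 0.82, while NT5E, the surface 5'-nucleotidase, was at -1.67 ± 0.22 and UCKL1 at 0.41. The median of its 12 measured genes was 0.12 (percentile 84.8). UMPS, which converts 5-FU to its nucleotide, was at -0.15, within its spot error of 0.20. DPYD, which degrades 5-FU, was not well above background on either array, and UPP1 had no probe matched by accession. The 12 genes of ribonucleotide reductase and the salvage kinases had a median of 0.25 (percentile 96.2) with none past 2-fold, among them HPRT1 at 0.78, RRM2 at 0.70, DCK at 0.68 and CMPK1 at 0.53 (other probe 0.13), while RRM2B was at -0.53.

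Of the 10 measured genes in the list of TYMS and its neighbours on chromosome 18, 7 lay below 0 and 3 above 0, TYMS among the latter. The median was -0.47 (percentile 0.52), with EMILIN2 at -0.89, TGIF1 at -0.78 and SMCHD1 at -0.68, whose other probe gave 0.61. This list no longer stood apart with the mean of a gene's probes (median -0.25) or without the filter on dim probes (median -0.0033). Of the 8 measured genes in the list of drug transporters, which also holds the vault protein MVP, none was 2-fold higher. ABCC3 and ABCC2 were 5.29-fold and 2.08-fold lower, MVP was at -0.64, ABCC10 at -0.39 (other probe -0.02) and ABCC1 at 0.17, and the list median was -0.28 (percentile 13.2). ABCG2 was not well above background on either array, and ABCB1 was so on the parental array only, with a bound of 1.20-fold.

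Genes of DNA replication were higher as a group. All 34 measured members lay above 0, 10 of them at least 2-fold, with a median of 0.62 (percentile 100). MCM4 and MCM5, subunits of the replicative helicase, were at 1.58 and 1.55, the GINS subunit GINS2 at 1.32 and the origin recognition subunit ORC6 at 1.27. Mitotic genes had a median of 0.33 (percentile 100), with 28 of 30 above 0 and 1 past 2-fold, the cyclin CCNA2 at 1.30. CCNB1 was at 0.93, and the kinases AURKA and BUB1 at 0.84 each. The median of homologous recombination and Fanconi genes was 0.27 (percentile 99.8), with 21 of 27 above 0, XRCC2 at 1.09, FANCF at 0.91, RAD51D at 0.85 and XRCC3 at 0.84. FANCF and RAD51D had other probes at 0.11 and -0.46, and the list did not stand apart under the stricter filter. Mismatch and base excision repair stood at 0.20 over 21 genes (percentile 97.9), which unmatched random lists did not set apart. In it the flap endonuclease FEN1 was at 1.20, the uracil glycosylase UNG at 0.96 and PARP1 at 0.76 (other probe 0.26), while NEIL1 was at -0.92. FEN1 and LIG1, the latter at 0.46, also belong to the DNA replication list, and the repair list was not read without them.

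Ribosomal genes formed groups of opposite direction. Of 36 ribosomal protein genes 33 lay below 0, with a median of -0.40 (percentile 0) and none past 2-fold. RPL3 was at -0.68, and RPL5 and RPS27 at -0.67 each. Factors of ribosome biogenesis had a median of 0.22 (percentile 99.4), with 25 of 30 above 0, and NIP7 at 1.47, NOLC1 at 0.53, BOP1 at 0.52 and UTP20 at 0.44.

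**Figure D2:**
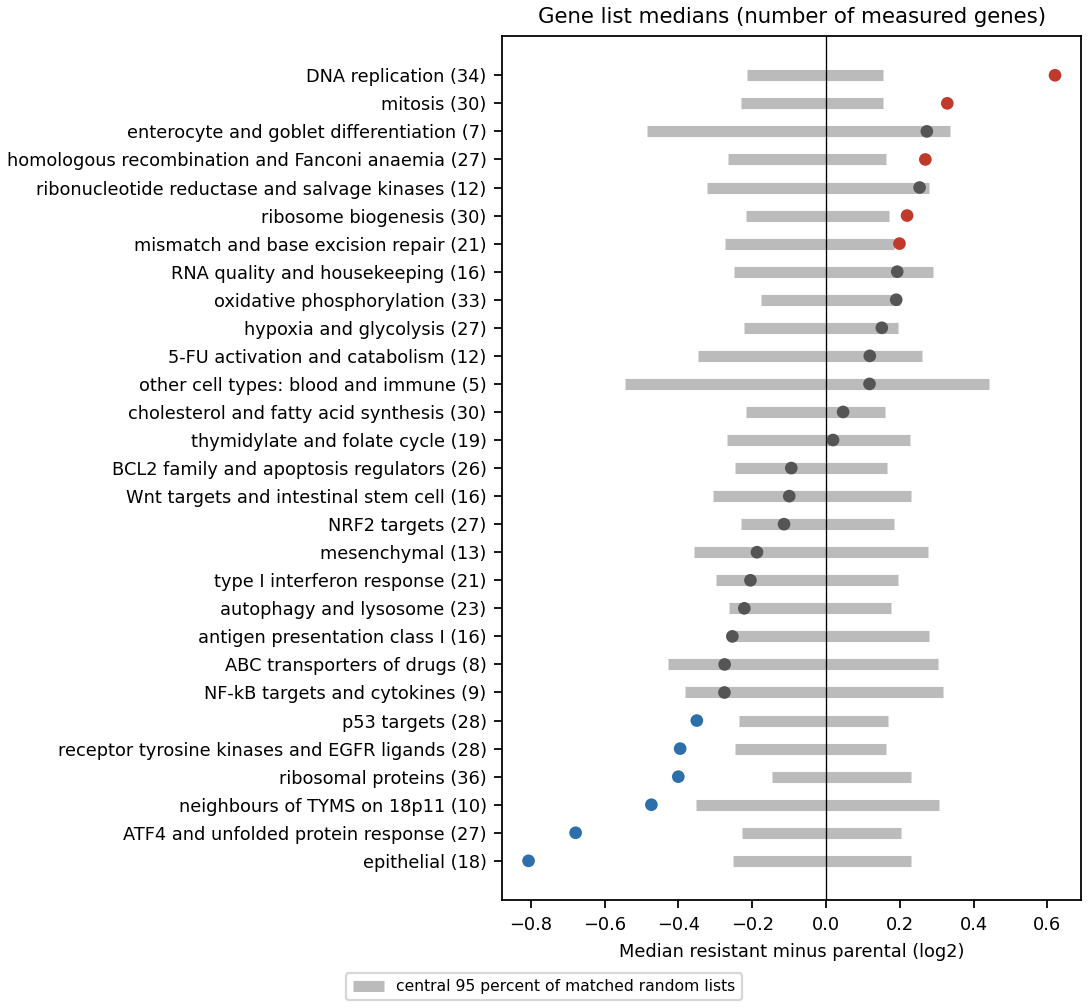
Each dot is the median log2 difference, resistant minus parental, over the measured genes of a list, whose number stands in brackets. Grey bars span the central 95 percent of 10000 random lists matched on level, red and blue dots are the 5 higher and 6 lower lists outside them, and the medians run from -0.81 for epithelial genes to 0.62 for DNA replication.

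Stress-response genes were lower. Of 27 measured targets of ATF4 and the unfolded protein response, 26 lay below 0 and 9 were at least 2-fold lower, with a median of -0.68 (percentile 0). Besides DDIT3 at -2.59 and TRIB3 at -2.41, DDIT4, an inhibitor of mTORC1, was at -1.81. The only member above 0 was CRELD2, an endoplasmic reticulum protein, at 1.73 ± 0.20. The members below 0 were not evenly lower. DNAJB9 at -0.01, DNAJC3 at -0.04 and HSP90B1 at -0.04 lay within their spot errors, while HSPA5 was at -0.79 and HERPUD1 at -0.62. ATF3, past 2-fold at -1.05, had other probes between -0.26 and 0.32. Targets of p53 had a median of -0.35 (percentile 0.16), with 23 of 28 below 0 and 4 at least 2-fold lower. These were the secreted factor GDF15 at -1.98, the pro-apoptotic BBC3 at -1.35, the death receptor TNFRSF10B at -1.24 and GADD45A at -1.21. The cell cycle inhibitor CDKN1A was at -0.27 ± 0.23, and MDM2 was at 0.14 on its brighter probe and -0.57 on the other. The 26 apoptosis regulators of the BCL2 list had a median of -0.09 (percentile 30.6), with HRK at -0.87, BCL2L11 at 0.81, XIAP at -0.69 and BCL2L1 at -0.14 ± 0.21. The other probes of BCL2L11 lay between -0.81 and 0.42. NRF2 targets had a median of -0.11 (percentile 21.1), with SLC7A11, which also belongs to the ATF4 list, at -1.18 and NQO1 at -0.90.

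Epithelial genes were the list furthest below 0, with a median of -0.81 (percentile 0), 17 of 18 below 0 and 7 at least 2-fold lower. CDH1, E-cadherin, was at -1.76 ± 0.21, the claudin CLDN7 was at -1.33, P-cadherin CDH3 at -1.32 and the splicing regulator ESRP1 at -1.31. Mesenchymal genes were not higher as a group. Their median over 13 genes was -0.19 (percentile 18.3), with ACTA2 at -1.27, TWIST1 at 1.10, CCN2 at -0.79 and COL1A1 at -0.67, and VIM, vimentin, was at 0.02 ± 0.21. Receptor tyrosine kinases and EGFR ligands had a median of -0.40 (percentile 0.02), with 22 of 28 below 0, the ligand AREG at -1.91, INSR at -1.12, and EREG and FGFBP1 at -0.89 each. The Wnt and stem cell list had a median of -0.10 (percentile 32.8), in which RNF43, a negative regulator of Wnt receptors, was at -1.88 and the secreted Wnt inhibitor DKK1 at 1.68, with CD44 at -0.95 and SOX9 at -0.87. Under the stricter filter its percentile was 0.995. Of 7 measured enterocyte and goblet genes KLF4 was at -1.56, DPP4 at -1.16, CDX2 at -0.77 and TFF1 at 0.54, with a median of 0.27 (percentile 94.8, and 98.1 with normexp and 99.7 with no filter on dim probes).

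The next groups lay inside the central 95 percent of random lists in the main setting. Some medians changed sign with a setting. Those of the Wnt, drug transporter, NF-kB and fibroblast lists were above 0 without the filter on dim probes, and that of hypoxia and glycolysis was below 0 in the series matrix. Spike-in and median scaling shift every gene alike, which by itself puts the BCL2, Wnt and NRF2 medians above 0 in the former and the thymidylate and folate median below 0 in the latter. The type I interferon list had a median of -0.21 over 21 genes (percentile 10.6), with IFITM1 at -1.87, PARP9 at -1.14, STAT2 at -0.95 and IFIH1 at -0.85. It went both ways, with 13 genes below 0 and 8 above 0, among the latter IFIT1 at 0.63 and ISG15 at 0.51. Under the stricter filter the percentile of the interferon list was 0.21. Class I antigen presentation had a median of -0.25 over 16 genes (percentile 2.62), with HLA-B at -0.82, HLA-F at -0.81 (other probe -0.26), B2M at -0.64 and CANX at 0.75 (other probe 0.30). It lay just inside the central 95 percent, and outside it with normexp (percentile 1.70), no filter on dim probes (1.64), the stricter filter (1.11) and the mean of a gene's probes (2.38). HLA genes are near-identical in parts, so their probes are uncertain. NF-kB targets had a median of -0.28 over 9 genes (percentile 9.09), with LIF at -0.76, SOD2 at 0.63, RELB at -0.56 and NFKB1 at -0.45. Hypoxia and glycolysis genes had a median of 0.15 over 27 genes (percentile 94.2) and went both ways, with the glycolytic enzymes LDHA at 1.13 and PGAM1 at 1.10 (other probe 1.57), NDRG1 at -1.31 and ANGPTL4 at -1.03. Oxidative phosphorylation had a median of 0.19 over 33 genes (percentile 96.5), with CYC1 at 0.74 and ATP5F1C at 0.70. Cholesterol and fatty acid synthesis had a median of 0.05 over 30 genes (percentile 77.9), with INSIG1 at 1.03, MVD at 0.90 and SCD at 0.68. Autophagy and lysosome genes had a median of -0.22 over 23 genes (percentile 5.19), with MAP1LC3B at -1.14, MCOLN1 at 0.87, CTSB at -0.81 and GABARAPL1 at -0.66.

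Markers of other cell types were few. Of the fibroblast list 4 genes were measured, with a median of -0.61 and no percentile, of the blood and immune list 5, with a median of 0.12 (percentile 71.7), and of the endothelial list 2, with a median of 0.15. Housekeeping genes had a median of 0.19 over 16 genes (percentile 90.3), with TUBB at 1.16, TUBA1B at 0.86 and B2M at -0.64.

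Along the chromosomes, 1 region lay beyond the shuffled limits of -0.56 and 0.46. It was on chromosome 6, ran over 81 measured genes from HDGFL1 to MOG and holds the large histone gene cluster, and its most extreme window had a median of 0.53. The 46 histone genes in it had a median of 0.57 with 40 above 0, and the 35 other genes a median of -0.04. H2AC4 was at 1.06, H2BC5 at 1.04 and H2AC6 at 1.02, each with a spot error of 0.21. H2AC13 was at 0.92 and H2BC12 at 0.96, with another probe of H2BC12 at -0.08. PRSS16, not a histone gene, was at -1.27 there, and its other probe at 0.49. Histone genes are close copies of each other, so single members are uncertain. The 3 most extreme windows that did not overlap included another in this region, from BTN2A1 to H3C12 with a median of 0.53, and 1 on chromosome 13, from UGGT2 to NAXD, with a median of -0.50 inside the shuffled limits. The lowest genes of the latter were GGACT at -1.48, the peptide transporter SLC15A1 at -1.31 and the ephrin EFNB2 at -1.19. Medians of whole chromosomes ran from -0.15 on chromosome 13 to 0.03 on chromosome 19.

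**Figure D3:**
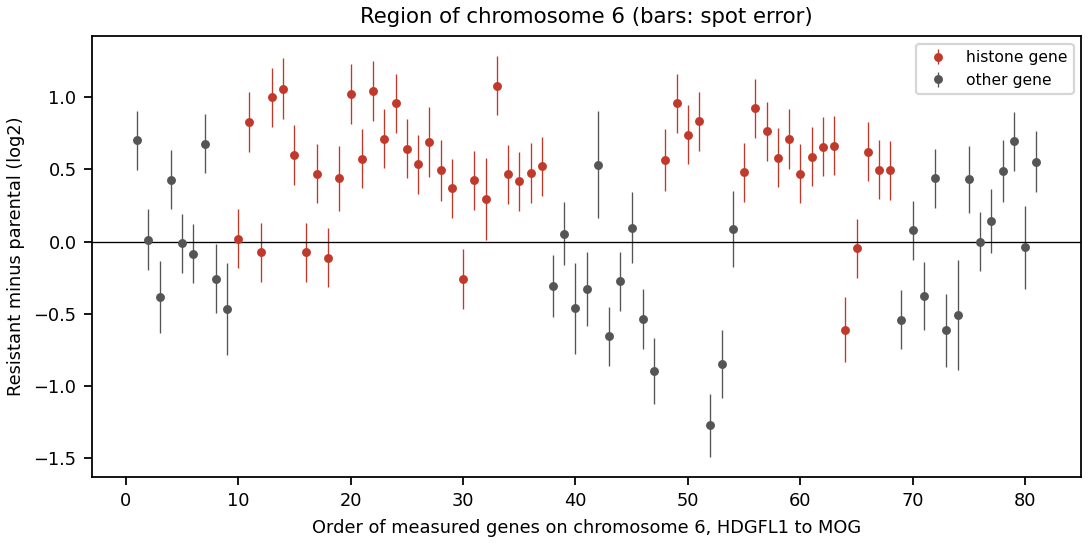
Each point is 1 of the 81 measured genes from HDGFL1 to MOG in their order on chromosome 6 (x axis), with resistant minus parental on the log2 scale (y axis). Bars are the spot error. Red points are the 46 histone genes, with a median of 0.57, and grey points the 35 others, with a median of -0.04.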

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

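Some tests below were chosen after the result was seen: those of the agreement of probes, of neighbouring spots, of ribosomal RNA, of the DNA replication list and of the scaling behind the ATF4 list.

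Transcripts without a symbol in the reference entered none of the report's comparisons, and their differences past 2-fold were one-sided. Of 4460 measured on both arrays, 361 were at least 2-fold higher in the resistant cells and 65 at least 2-fold lower. Among 2172 long intergenic RNAs the numbers were 187 and 19. These counts were made in the main setting only. Among named genes the share of higher calls ran from 39.3 to 66.4 percent over the settings. Neither agreement between probes nor cross-hybridization was tested for the unnamed transcripts, so brighter probes cannot be told apart from higher transcripts.

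The genes at least 2-fold higher in the resistant cells raise the question whether their transcripts or only single probes were brighter. Of the 79 such genes with several measured probes, 30.4 percent had other probes with a median of 0.5 or more, against 52.9 percent of 51 genes in the lower direction. In 25 of the 79 the median of the other probes was 0 or below, and in 11 of the 51 it was 0 or above. Signal of single probes may therefore account for part of the higher genes, though probes can also measure different isoforms. A bright area of the resistant array around most probes of these higher genes is argued against. The 2644 spots next to these probes had a median of 0.030 ± 0.01 (bootstrap SE). This pooled median cannot exclude bright patches around a minority of the probes. The software marked 106 spots on the resistant array and 6 on the parental as non-uniform, and these were left out. Other labelling or hybridization of ribosomal RNA stays open: its 6 probes had a median of 1.68, but only those of 28S were above 1. Without probe sequences, cross-hybridization of the highest probes, with 28S or other RNA, was not tested.

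The histone genes of chromosome 6 were higher by a median of 0.57. Gain of the whole region is argued against by the 35 other genes in it, with a median of -0.041. More labelling of RNA without a poly(A) tail cannot be told apart from higher expression, since 30 small RNA genes of that kind had a median of 0.30, between the values set for either outcome, with 21 of 30 above 0, and ran from -0.85 to 1.41. A larger share of cells in S phase is a possible explanation as well, and the DNA replication list, whose transcripts carry a poly(A) tail, had a percentile of 100. Cross-hybridization between histone copies was not tested.

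Targets of ATF4 and of p53 were lower together. The scalings tried do not account for the ATF4 list. Its median was -0.53 ± 0.14 (bootstrap SE) at its highest, with spike-in scaling, over the main setting and 7 alternatives. At its lowest, with quantile normalization, it was -0.74. Median, detected-spot and spike-in scaling shift all genes alike, by at most 0.15 in size, so they could not bring the main median of -0.68 near 0. With the other alternatives the median stayed at -0.55 or lower. The SE treats the genes of the list as varying independently. GDF15, SESN2, TNFRSF10B, BBC3, PMAIP1 and GADD45A, which ATF4 or its target DDIT3 can also induce, include all 4 p53 targets past 2-fold. Without these 6 the p53 list had a median of -0.30 and a percentile of 1.34 over 22 genes, 17 of them below 0 and 0 past 2-fold lower. The rest of the list thus still lay lower without these 6 genes. The random lists draw genes singly, so this percentile does not hold for targets that vary together. What lowered the rest of the list, and its 4 genes past 2-fold, stays open. A difference in culture state, such as density or nutrients at harvest, cannot be told apart from the resistant state, because each group has 1 array. Resistance itself stays open in the same way.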

How the results depend on the processing

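An alternative scaling to the 75th percentile of detected spots, spike-in scaling beyond the counts of genes, and the agreement of probes were added after seeing the data. Counts of genes moved most with normexp and the filter. Normexp on the median signal gave 158 higher and 89 lower genes and 10 genes with a bound of 2-fold or more, against 213. Its offset of 50 shrinks differences of dim genes, but the changes of background and of input signal were not run apart. No filter on dim probes gave 951 and 926, and the stricter filter, which keeps fewer genes, 178 and 132. Spike-in scaling gave 221 lower genes and 436 higher, as its shift of 0.15 implies. Of the 296 higher genes 291 and of the 360 lower genes 356 were shared with cyclic loess. Leaving out genes whose other probes fell short kept 241 and 336. Only 79 of the higher and 51 of the lower genes had another measured probe, and 24 and 27 of these passed. Genes with a single measured probe were kept without a check. Between 11 and 13 lists stood apart over 11 alternatives, and 8 of the 11 did so under each. Median, detected-spot and spike-in scaling could not change this count, since a uniform shift moves a list and its random lists alike. None of the 11 lists apart in the main setting changed sign. Of the other lists 5 did under a setting that does not shift all genes alike. Antigen presentation joined under 4 alternatives, enterocyte genes under normexp and no filter, Wnt and interferon genes under the stricter filter, and oxidative phosphorylation with unmatched lists. The histone region was split into 2 in the series matrix and 2 with windows of 15 genes. The cause was not tested. For the counts of bounds, other filters and the mean of probes give no separate value. No named gene past 2-fold changed sign under any alternative run. Of the values of all named genes under alternatives, 1429 moved by less than the spot error and 101 by more, 75 of these under normexp. Many of the 1429 could not have moved by more. Median, detected-spot and spike-in scaling shift all genes alike, by at most 0.15 in size, under the lowest spot error of 0.20. The other filters mostly keep a gene's brightest probe, and the mean of probes leaves a gene with 1 probe unchanged. No paired analysis was possible because each group has 1 array. The spot error of a difference ran from 0.20 to 0.45. It stayed near 0.20 for bright genes whatever their level, with a median of 0.21 over all genes. Signal over background raised it for dim probes only, such as that of CD68 at 0.42.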

Other observations

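TYMS can be set beside the DNA replication genes, which are transcribed in the same phase of the cell cycle. Of the 34 measured replication genes, 10 had a larger difference than TYMS at 1.03. No test separates a specific difference of TYMS from that of the replication genes.

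Of the 30 measured small RNA genes without a poly(A) tail, 21 lay above 0, 3 were at least 2-fold higher and 0 at least 2-fold lower. RN7SK, which holds back transcription elongation, was at 1.41, SNORD17 at 1.10 and SNORA62 at 1.08, while SCARNA12 was at -0.85 and RNU12 at -0.69. These were chosen after their values were seen.

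The 10 spike-in probes lay between -0.25 and -0.07 relative to the 75th percentile. Of 96 further control probes for another set of spike-ins, 1 was well above background on most spots of each array.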
